A study of Caenorhabditis elegans with 4 samples.

How the data were processed

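Chromatin from mixed-stage embryos of the wild-type Caenorhabditis elegans strain N2, a population of males and hermaphrodites, was immunoprecipitated with SDQ2966, an affinity-purified rabbit polyclonal antibody raised against a fragment of MIS-12. Per the labels' protocols, live embryos were fixed with formaldehyde, the chromatin was sheared by sonication, and a portion of each extract was kept as input DNA. The labels list 4 samples, 2 ChIP samples (replicates 1 and 2) and 2 input samples (replicates 1 and 2). They do not say whether the replicates came from separate cultures, so any agreement or spread between them may be technical.

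The data analysed were 3 lists of peaks, 1 for each ChIP sample and 1 for the series as a whole, which is called the combined list here. Per the file headers, all coordinates refer to genome build WormBase WS220, the ChIP sample lists were called with MACS (version not stated) and the combined list with MACS v2. This build line could not be checked against chromosome lengths. The last peaks of the combined list on I, III and IV ended at 15072435, 13783731 and 17493824, beyond the last replicate peaks, and may run past the ends of the chromosomes in WS220. Between matching peaks, the median difference of midpoints (combined minus replicate) was -23 bp for replicate 1 and -16.8 bp for replicate 2 in the first 20% of chromosomes. In the last 20% it was -15 and -15.5 bp. The change was smaller than the interquartile range of single differences, but that range is not the error of a median. Pairs were also pooled over chromosomes, so the comparison cannot decide whether the lists share a build. The aligner, the read depth, the calling threshold and the control given to the peak caller are not given in the sources used here. Nor do the sources say whether the combined list came from pooled reads of both replicates. The authors' deposited value for each peak is a score whose definition is not stated. In the ChIP sample lists it began just above 50 and 22 and 34 peaks stood at exactly 3100, as a value with a limit would, although single peaks lay above it (up to 3121 and 3148). In the combined list it ran from 1.31 to 58.3, on another scale. Scores were therefore compared only as ranks or within a list, or between the 2 ChIP sample lists, which share a caller. The files hold the first and last base of each peak, counted from 1, and give no read counts, so the depth behind each peak is unknown. The input samples were not analysed here, and no level of background could be set beside the peaks.

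Peaks were compared by position with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. A peak was called shared when it had at least 1 bp in common with a peak of the other list. The chance level was set by rotating one list around each chromosome by a random distance 100000 times, which keeps peak widths and spacing, and the one-sided permutation p is the share of rotations with at least as many shared peaks. With 100000 rotations or resamples the smallest p is 1e-05. Differences of median scores and correlations were tested with two-sided permutation tests of 100000 resamples. Since no chromosome lengths came with the lists, the highest peak end of any list served as the length of each chromosome. Peaks per Mb carry exact Poisson 95% intervals. The X chromosome was compared with the 5 autosomes by an exact conditional binomial test, two-sided. The middle 33.3% of each chromosome was compared with its ends by the mean log2 ratio of peaks per Mb over the 6 chromosomes, with 0.5 added to each count, and an exact permutation test of all 64 sign flips, two-sided, which cannot go below p = 0.0313. Grouping was measured as the percent of peaks whose midpoint lay within 5 kb of another, against 100000 uniform placements (one-sided). Shares carry Wilson 95% intervals. All intervals cover counting error only, and neighbouring peaks are not independent, so tests over peaks give p-values that are too small. For this reason peaks of a list with at most 2 kb between them were also joined into loci, a choice made after the data were examined. The 6 comparisons of the lists, their tests and most alternatives were fixed before the data were examined. Joining into loci, leaving out scores of 3000 or more, restricting to peaks found in both replicates, the comparisons of chromosome III, of score quartiles, of 1-Mb windows and of chromosome ends, and the tests of explanations were added afterwards. The comparison of X by covered sequence in the combined list was fixed beforehand, and the other ratios of covered sequence were added. Ratios of covered sequence carry 95% bootstrap intervals from 10000 resamples of loci.

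The statistics were tested on 100 simulated pairs of lists with the real widths. With independent placement, p fell under 0.05 in 2 simulations for the overlap, 2 for the X chromosome, 3 for the middle of chromosomes and 1 for grouping. Each simulated peak was placed on its own, so the simulated lists lack the grouping of the real lists. They do not show how often the tests pass by chance when peaks are grouped. With 30% of replicate 1 peaks copied into replicate 2, the mean share found was 30.8% and all 100 simulations passed. With the density on X halved, the mean ratio was 0.50 and all 100 passed. With the density in the middle halved, the mean log2 ratio was -1.01 and 99 passed.

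By the rule fixed beforehand, the peaks named are the 25 of the combined list with the highest score that overlap both replicates, the first 10 in full. Other regions named were chosen after their values were seen. The gene table at hand describes assembly WBcel235, not WS220, so no peak was assigned to a gene, and the planned comparisons of gene features, gene lists and sequence composition were not made.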

Results

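MIS-12 is a subunit of the kinetochore, the protein assembly that links chromosomes to spindle microtubules. In C. elegans, whose chromosomes are holocentric, kinetochores form along the whole length of each chromosome. ChIP-seq with an antibody against MIS-12 was used to ask where on the chromosomes of mixed-stage N2 embryos the protein was recovered. Replicate 1 gave 694 peaks that covered 494 kb, and replicate 2 gave 746 peaks that covered 496 kb. The combined list held 1251 peaks over 752 kb. Most peaks were narrow, with a median width of 332 bp in replicate 1, 294 bp in replicate 2 and 275 bp in the combined list. A minority of wide regions held much of the covered sequence. Peaks of 2000 bp or more made up 7.93% of replicate 1 peaks, 6.70% of replicate 2 peaks and 6.16% of combined peaks, and held 43.3%, 40.9% and 38.6% of the covered sequence. The widest nuclear peak of the combined list spanned 11136 bp at the right end of chromosome I (I, 15060222 to 15071357, score 35.2). It was matched by a single peak in each replicate (15060215 to 15071349 in replicate 1 and 15060221 to 15071348 in replicate 2), both with a score of 3100. The number of reads behind the peaks is unknown. Repeated sequence and copy number at the right end of chromosome I were not examined, and no input profile was set beside the 11136-bp peak. Its width and scores alone do not show recovery of MIS-12 there.

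The strongest regions were shared by both replicates. The 25 highest-scoring peaks of the combined list all overlapped peaks of both replicates. The highest, on X (11441825 to 11443761, 1937 bp), scored 58.3 and had scores of 1707 in replicate 1 and 2143 in replicate 2. It was followed by a 2760-bp peak on III (3334256 to 3337015, score 56.0), a 3221-bp peak on IV (3206315 to 3209535, score 55.6) and a 2333-bp peak on IV (12730376 to 12732708, score 52.1). Each of these 3 peaks reached 3100 in both replicates. A 948-bp peak on I (670546 to 671493) and a 608-bp peak on IV (12891245 to 12891852) both scored 52.0. Their replicate scores were further apart, at 431 and 1661 for the peak on I and 484 and 1775 for the peak on IV. Next came a peak on V (1637827 to 1639093, score 50.3), with 1069 in replicate 1 and 3100 in replicate 2. A peak on X (5056150 to 5057273, score 49.7) had 2766 and 2847. Another on I (933380 to 934831, score 48.9) stood at 3100 in both replicates. The last of the first 10, on I (4540300 to 4547789), was 7490 bp wide, scored 48.5 and held replicate scores of 2588 and 2912. The other 15 peaks scored 42.2 to 48.2. Of all 25, 5 lay on I, 2 on II, 3 on III, 6 on IV, 4 on V and 5 on X, and their median width was 1755 bp.

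Of the replicate 1 peaks, 422 of 694 (60.8%, Wilson 95% interval 57.1 to 64.4) overlapped a replicate 2 peak. In the other direction 419 of 746 did (56.2%, 52.6 to 59.7). After rotation the mean shares were 0.82% and 0.83%, and no rotation exceeded 13.4% and 12.7% (permutation p = 1e-05 in both directions, the smallest possible). By covered sequence, the 2 lists shared 378 kb, or 61.9% of the bases covered by either. Sharing depended on score. In the highest quartile of replicate 1 scores 171 of 174 peaks (98.3%, 95.1 to 99.4) were found in replicate 2, against 43 of 174 (24.7%, 18.9 to 31.6) in the lowest. In replicate 2 the corresponding counts were 185 of 187 (98.9%, 96.2 to 99.7) and 38 of 187 (20.3%, 15.2 to 26.7). The median score in replicate 1 was 166 for shared and 64.4 for unshared peaks, and in replicate 2 it was 305 and 74.1 (permutation p = 1e-05 for each). Wide peaks were nearly all shared, with 52 of 55 peaks of 2000 bp or more in replicate 1 and 49 of 50 in replicate 2. The strongest replicate 1 peak without a counterpart in replicate 2 lay on V (3434614 to 3441121, 6508 bp, score 745). The strongest in replicate 2 without a counterpart covered the mitochondrial genome from base 3 to base 13379 (score 1653).

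**Figure D1:**
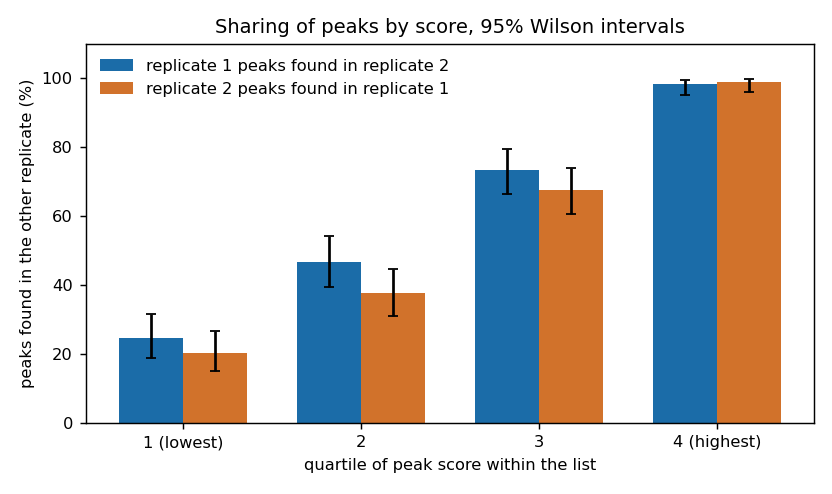
Percent of peaks (y axis) of replicate 1 (blue) and replicate 2 (orange) that overlapped a peak of the other replicate by at least 1 bp, by quartile of the peak score within each list (x axis). Bars are shares and whiskers 95% Wilson intervals; sharing rose from 24.7% and 20.3% in the lowest quartile to 98.3% and 98.9% in the highest.

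Among shared peaks, the scores of the 2 replicates tended to rise together, although single pairs lay far apart. A peak on III (2077592 to 2082666) scored 2123 in replicate 1 and 297 in replicate 2. One on IV (12169265 to 12169611) scored 74.9 and 1730. The next replicate 1 peak there (12169669 to 12170682, score 244) was set against the same score of 1730. A replicate 2 score can thus recur for neighbouring replicate 1 peaks, and part of such a gap may come from how a region was split. Across the 422 replicate 1 peaks with a counterpart, the score and the highest overlapping replicate 2 score had a Spearman rho of 0.72 and a Pearson r of 0.75 on the log10 scale (permutation p = 1e-05 for each, adjusted p = 1e-05 over the 4 correlations computed). This is a correlation across peaks, which are not independent replicates. Among the 329 pairs that covered at least 50% of each other, rho was 0.84. In 241 of these pairs (73.3%) the replicate 2 score was the higher, and the median ratio of replicate 2 to replicate 1 was 1.48. With the read depth and the definition of the score unknown, the ratio cannot be read as stronger enrichment in replicate 2. Over 97 complete 1-Mb windows of the 6 nuclear chromosomes, the numbers of peaks in the 2 replicates had a rho of 0.73 and an r of 0.72 (permutation p = 1e-05 for each).

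**Figure D2:**
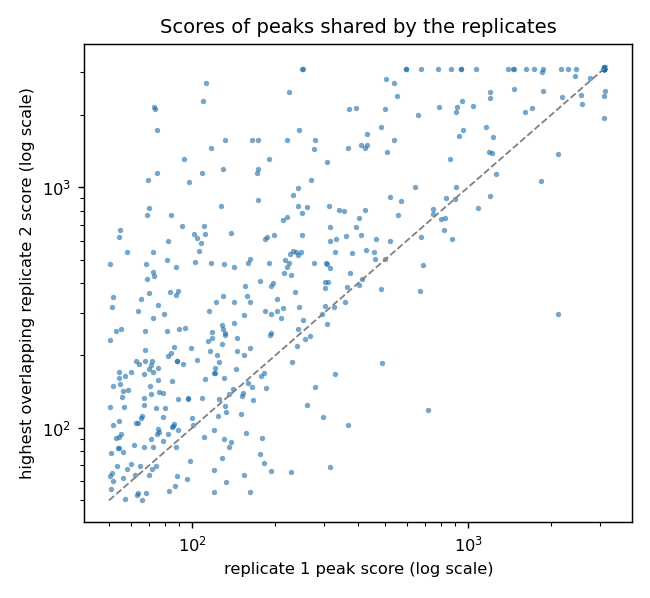
Score of each shared replicate 1 peak (x axis, log scale) against the highest score of the replicate 2 peaks it overlapped (y axis, log scale), with the line of equality dashed. The 422 points follow a rising trend (rho 0.72), most lie above the line, and the values stop near 3100 on both axes.

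The combined list held many peaks beyond those of the replicate lists. Of its 1251 peaks, 338 (27.02%, 24.6 to 29.5) overlapped peaks of both replicates, 106 (8.47%) of replicate 1 only and 160 (12.8%) of replicate 2 only. The other 647 peaks (51.7%, 49.0 to 54.5) overlapped neither, a share that was 70.9% when 50% reciprocal overlap was required. It was 47.0% when every list was cut to its highest-scoring 50%, which also removes replicate peaks that combined peaks could overlap. Set against the full replicate lists, 85.9% of combined peaks in the highest score quartile overlapped replicate 1 and 90.7% replicate 2. In the lowest quartile these shares were 10.5% and 10.2%. The peaks found in both were stronger and wider, with a median score of 16.1 and a median width of 731 bp, against 3.98 and 201 bp for those found in neither (difference of median scores 12.1, permutation p = 1e-05). The 338 peaks held 60.7% of the sequence covered by the combined list and 69 of its 77 peaks of 2000 bp or more. The 647 peaks held 21.4% and none of these 77. The strongest peak found in neither replicate scored 25.6 and was the last of chromosome I (15071697 to 15072435), just beyond the 11136-bp peak at that end. The next lay on IV (8574488 to 8574783) and scored 12.7. Of the peaks shared by the replicates, the combined list held 405 of 422 in replicate 1 (96.0%) and 401 of 419 in replicate 2 (95.7%). It held 135 of the 272 replicate 1 peaks that were absent from replicate 2 (49.6%) and 278 of the 327 replicate 2 peaks that were absent from replicate 1 (85.0%). These last shares differed (Fisher's exact test, two-sided, p = 9.96e-21, counting error only).

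Peaks lay on every nuclear chromosome and formed groups. In the combined list 61.5% of the 1248 nuclear peaks had another midpoint within 5 kb, against a mean of 11.8% after uniform placement (permutation p = 1e-05). The shares were 57.6% in replicate 1 and 72.1% in replicate 2, with 6.88% and 7.60% after uniform placement (permutation p = 1e-05 for each). The group with the most peaks lay on III (7405272 to 7441171), with 43 combined peaks in 35900 bp. Replicate 2 had 39 peaks there, in 1 group (7405316 to 7440353), and replicate 1 had 13 peaks, in 7 loci. The largest group of replicate 1 had 28 peaks on III (13584176 to 13598870), where replicate 2 had 21 (13584205 to 13599327). In the combined list groups of 24 and 16 peaks lay near each other on IV (6708689 to 6730487 and 6686749 to 6700284), and 19 peaks formed a group on V (6075362 to 6089295). Joining peaks no more than 2 kb apart left 435 loci in replicate 1, 356 in replicate 2 and 754 in the combined list, of which 116, 123 and 207 held several peaks. Of these loci in the combined list, 11.3% (85 of 754) had a neighbour within 5 kb, against a mean of 7.24% after uniform placement (permutation p = 0.00212).

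**Figure D3:**
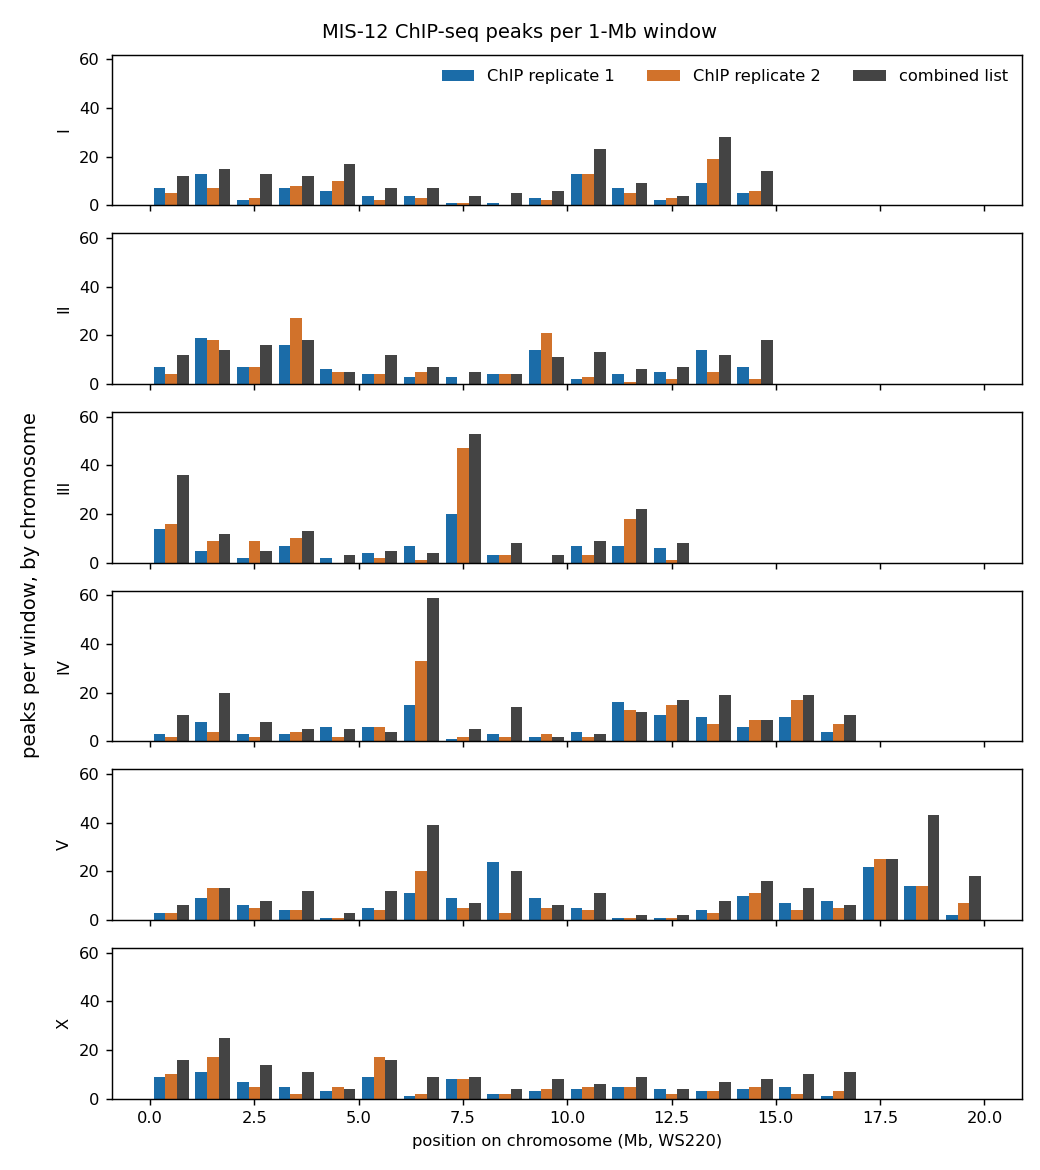
Number of peaks (y axis) in each complete 1-Mb window along chromosomes I to X (x axis, Mb in WS220), with replicate 1 in blue, replicate 2 in orange and the combined list in dark gray. In replicate 2 and the combined list the fullest complete windows are on III from 7000001 to 8000000, with 20, 47 and 53 peaks in the same order, and on IV from 6000001 to 7000000, with 15, 33 and 59 in replicate 1, replicate 2 and the combined list. Among complete windows, replicate 1 has its maximum of 24 on V from 8000001 to 9000000. The incomplete last window of each chromosome is left out. That of III held a group of 28 replicate 1 peaks, more than any complete window of that list, and groups of 21 and 20 replicate 2 peaks.

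The number of peaks per Mb was lowest on X and highest on III. The X chromosome had the fewest peaks per Mb in each list, with a mean of 5.23 ± 0.44 (SD, n = 2 replicates) against 7.60 ± 0.34 on the autosomes. The ratio of X to autosomes was 0.67 (95% interval 0.53 to 0.84, exact binomial p = 0.000272, adjusted p = 0.00163) in replicate 1. It was 0.71 (0.57 to 0.87, exact binomial p = 0.00106, adjusted p = 0.00319) in replicate 2. In the combined list it was 0.77 (0.65 to 0.90, exact binomial p = 0.000825, adjusted p = 0.00319). Adjustment was over the 12 tests of X and III in peaks and in loci. An exact permutation over the 6 chromosomes cannot give a p below 0.167, so a test that takes chromosomes as the unit cannot decide. Chromosome III was the densest in each list, with 9.21 peaks per Mb in replicate 1, 12.1 in replicate 2 and 14.9 in the combined list. Its ratio to the other autosomes was 1.32 (1.08 to 1.61), 1.73 (1.45 to 2.07) and 1.18 (1.01 to 1.37), with exact binomial adjusted p = 0.0156, 6.34e-08 and 0.0735. III was tested because it had been seen to be the densest, which these p-values do not account for. Counted as loci, III had no significant excess, with ratios of 1.01 (0.76 to 1.33), 0.88 (0.62 to 1.21) and 1.04 (0.84 to 1.28). The ratio for X also moved towards 1 when loci were counted, to 0.78 (0.58 to 1.02), 0.85 (0.63 to 1.14) and 0.81 (0.66 to 0.996), and no adjusted p passed 0.05 (0.102, 0.397 and 0.0768, exact binomial tests). By covered sequence per Mb, the ratio of III to the other autosomes was 1.21 (bootstrap 95% interval 0.73 to 1.91), 1.41 (0.77 to 2.36) and 1.40 (0.80 to 2.30) in replicate 1, replicate 2 and the combined list. That of X to autosomes was 0.89 (0.54 to 1.36), 0.94 (0.57 to 1.46) and 0.86 (0.56 to 1.26), and all of these intervals include 1. Among the 338 combined peaks found in both replicates the ratio for X was 0.85 (0.62 to 1.14, exact binomial p = 0.318).

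**Figure D4:**
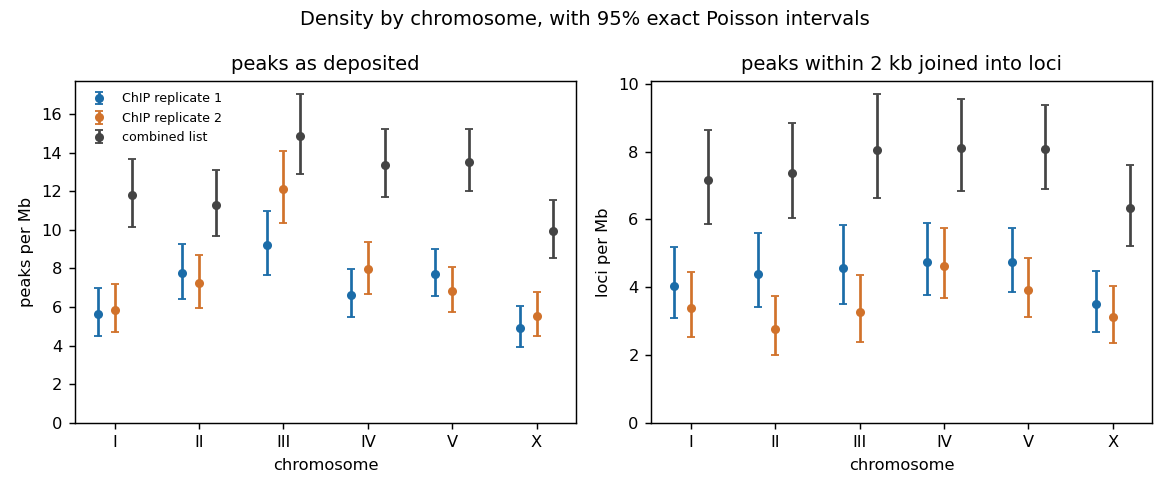
Peaks per Mb (left, y axis) and loci per Mb (right, y axis) on each chromosome (x axis) in replicate 1 (blue), replicate 2 (orange) and the combined list (dark gray), with exact Poisson 95% intervals as whiskers. Chromosome III stands highest for peaks, at 9.21, 12.1 and 14.9 per Mb, and not for loci.

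Along the chromosomes, peaks were sparser in the middle on some chromosomes and not on others. In the combined list the middle 33.3% of chromosome I had 5.77 peaks per Mb against 14.8 at its ends, and V had 8.03 against 16.3. II (7.68 against 13.1) and X (7.46 against 11.2) lay in the same direction. IV had the opposite, with 16.3 in the middle and 11.9 at the ends, and III had 15.7 and 14.5. The mean log2 ratio of middle to ends was -0.52 ± 0.68 (SD over 6 chromosomes), which was not significant (exact permutation p = 0.125). The mean was -0.41 ± 0.58 in replicate 1 and -0.64 ± 0.99 in replicate 2 (exact permutation p = 0.156 and 0.219). Counted as loci, the middle had fewer per Mb on all 6 chromosomes in every list. The difference was uneven in replicate 1, from 1.791 in the middle against 5.175 at the ends on I to 4.588 against 4.803 on V. In the combined list the ratio was -0.80 ± 0.21, with 4.58 loci per Mb in the middle and 8.46 at the ends of I, 3.94 and 9.06 on II, 5.22 and 9.47 on III, 5.83 and 9.26 on IV, 5.88 and 9.18 on V, and 4.58 and 7.21 on X. Replicate 1 loci gave -0.53 ± 0.54 and replicate 2 loci -0.73 ± 0.35. Each of these 3 tests reached the smallest p the design allows (exact permutation p = 0.0313). The arm and centre domains of a published recombination map were also used in place of the middle and the ends. Their boundaries were entered from memory, rounded to 0.1 Mb. In these domains the ratio for combined peaks was -0.43 ± 0.25 (exact permutation p = 0.0313), below 0 on all 6 chromosomes. The replicates gave -0.42 ± 0.50 and -0.49 ± 0.37 in these domains (exact permutation p = 0.125 and 0.0625), below 0 on 4 and 5 chromosomes. Loci in these domains gave -0.47 ± 0.49 in replicate 1 (exact permutation p = 0.0938), -0.62 ± 0.25 in replicate 2 and -0.87 ± 0.18 in the combined list (exact permutation p = 0.0313 for each of these 2), below 0 on 5, 6 and 6 chromosomes. Adjusted over the 12 tests of this kind, those with an exact permutation p of 0.0313 had an adjusted p of 0.0625 and none passed 0.05.

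The left ends of the nuclear chromosomes carried peaks. Both replicates had a peak within the first 1000 bp of all 6 chromosomes, against a mean of 0.036 and 0.035 chromosomes after rotation (permutation p = 1e-05 for each). The first peak of each chromosome began at base 1 to 6. On I they reached base 505 in replicate 1 (score 501) and base 507 in replicate 2 (score 503), and on X base 338 (score 296) and base 329 (score 298). The combined list had such peaks on 4 of the 6 chromosomes, I, II, V and X (permutation p = 1e-05). Its first peak began at base 55760 on III and at base 8478 on IV. The rotations test only the position of these peaks. Repeated sequence and copy number at the ends were not examined, and no input profile was set beside them. The peaks are therefore not shown to be recovery of MIS-12 at chromosome ends. The right ends could not be tested in the same way, since the highest peak end served as the chromosome length. On each nuclear chromosome the last replicate peaks ended before the last combined peak. On V they ended at 20870526 and 20437916 against 20924004, and on X at 17311798 and 17311824 against 17691462. On the mitochondrial genome, the combined list had 3 peaks, replicate 2 had 1 and replicate 1 had none.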

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

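Of 40 recomputed values under other settings, 33 kept their reading: a value with a test kept its direction and its side of 0.05 by unadjusted p, and a value without a test stayed within the interval of the value reported. The ratio of X for loci is among them at an unadjusted exact binomial p of 0.0448, but its adjusted p was 0.0768. The ratio of X by covered sequence is among them without a test, and its own bootstrap interval (0.56 to 1.26) includes 1, so it does not show a lower density on X. Grouping is among them for loci, but there the share fell from 61.5% of peaks to 11.3% of loci, against 7.24% after uniform placement. Joining peaks into loci, leaving out scores of 3000 or more, and restricting to peaks found in both replicates were chosen after the data were examined. The overlap of the replicates stayed far above chance in each setting run, at 47.4% to 77.2% of replicate 1 peaks and 44.1% to 70.6% of replicate 2 peaks. The rank correlation of scores ranged from 0.62 (without scores of 3000 or more) to 0.84. The percent of combined peaks found in both replicates moved from 27.02% to 34.4% when each list was cut to its highest-scoring 50%. That cut also removes replicate peaks, so 34.4% is not the share of strong combined peaks found in the full replicate lists. The percent was 16.3% with 50% reciprocal overlap, 24.5% with midpoints within 500 bp and 31.5% for loci. The X to autosome ratio was 0.85 and no longer significant among combined peaks found in both replicates, where fewer peaks were tested, and 0.86 by covered sequence, where the replicate lists gave 0.89 and 0.94. The log2 ratio of middle to ends passed 0.05 before adjustment at -0.43 with the arm and centre domains of a published recombination map (boundaries entered from memory, rounded to 0.1 Mb) and at -0.80 for loci, both at the smallest exact p of 0.0313, and neither passed after adjustment (0.0625); the cause was not tested. It was nearer 0 at -0.24 in the 50% of peaks with the highest scores and at -0.32 among combined peaks found in both replicates, where 3 of 6 chromosomes had the lower middle, neither significant (exact permutation p = 0.375 and 0.469). Using 1 replicate list in place of the combined list gave X to autosome ratios of 0.67 to 0.71, log2 ratios of middle to ends of -0.64 to -0.41 and 57.6% to 72.1% of peaks with a neighbour. Leaving out mitochondrial peaks moved none of the nuclear comparisons, by construction, so those values are no check although they count among the 33. Uniform placement in the overlap changed only the chance level, not the share. The overlap, the score correlation and the comparison with the combined list need both replicates, so neither could be left out there. For grouping, rotation was not run as another placement because it leaves the spacing as it is. The settings for gene features, gene lists and sequence composition were not run, for want of a genome or annotation of WS220. No paired analysis was possible because the input samples that share the replicate numbers were not analysed here. With the depth of the libraries unknown, a peak absent from one list cannot be read as absence of signal.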

Other observations

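All tests of explanations here were chosen after the lists had been examined. The tests of random placement, of loci within 20 kb and of X in the combined loci were set down before those values were computed, and the tests of score, of X in the replicate loci, of III and of loci shifted by up to 1 Mb were chosen after the result was seen.

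The combined peaks on V between 18000001 and 19000000 numbered 43 and formed 23 loci, the most loci of any complete 1-Mb window of that list, against 14 peaks in each replicate. On V between 8000001 and 9000000 the replicates differed, with 24 peaks in 11 loci in replicate 1 and 3 peaks in 2 loci in replicate 2. On III the group at 13584182 to 13592167 was a single 7986-bp peak in the combined list, and was split into 18 peaks in replicate 1 and 13 in replicate 2. In the gene order of assembly WBcel235, 4 of the last 14 annotated genes of chromosome I are ribosomal RNA genes, out of 5 on that chromosome; the widest combined peak was the next to last of chromosome I in WS220. The position of those genes in WS220 was not examined.

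In the lists as deposited, 51.7% of the combined peaks overlapped neither replicate list. Random placement of all 647 peaks was argued against, since 220 of them (34.0%) lay within 5 kb of a replicate peak, against a mean of 6.60% when they were shifted by up to 1 Mb (permutation p = 1e-05). The test does not say how many of the 647 were placed at random, and many of the rest may have been. A weaker threshold in the combined list stays open. A combined peak found in a replicate list outscored one found in neither with a probability of 0.84, but this restates the difference in score that raised the question and decides nothing. Whether pooled reads, another caller version or another threshold was behind these peaks is not stated in the sources.

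Peaks within 5 kb of each other may in part be wide regions called in pieces no more than 2 kb apart, as at the group on III above. As the whole cause, pieces this close together were argued against, since after joining, 35.9% of the 754 combined loci had another locus within 20 kb, against 26.0% after uniform placement (permutation p = 1e-05). Within 5 kb, the distance of the pattern itself, the share of loci was 11.3% against 7.24% (permutation p = 0.00212). For the 20-kb share of 35.9%, each locus was also shifted on its own by up to 1 Mb, which keeps the regional density. The mean share within 20 kb was then 28.5% (permutation p = 0.0001, the smallest that 10000 shifts can give). The 5-kb share was not set against such shifts. Wide regions called in pieces more than 2 kb apart stay open, since joining leaves such pieces as neighbouring loci. The group on III at 7405272 to 7441171 was 1 locus in replicate 2 and 7 loci in replicate 1. Repeated sequence and copy number also stay open, since no genome and no input profile were examined. The design holds no group that would test a biological explanation.

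Whether the high peak density of chromosome III comes from groups of neighbouring calls counted peak by peak stays open. In replicate 2 the ratio of III to the other autosomes went from 1.73 for peaks to 0.88 for loci, but by covered sequence, which splitting does not raise, it was 1.41 with an interval from 0.77 to 2.36. For X in the combined list, the upper bound of the ratio for loci was 0.996. A bound below 1 had been set as the mark against the same explanation as the whole cause. The margin was narrow, and the adjusted p of 0.0768 (exact binomial test) does not keep it. By covered sequence the ratio was 0.86, with an interval from 0.56 to 1.26, so the explanation is not settled for this list. In the replicate lists it stays open, since the ratio moved towards 1, from 0.67 to 0.78 in replicate 1 and from 0.71 to 0.85 in replicate 2, with an upper bound of 1.02 in replicate 1. Whether X differs for a reason tied to MIS-12, to mappable sequence or to X copy number in a population with males was not tested.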
